A study of Cardamine sp. SIM-2007 with 7 samples.

How the data were processed

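The values used were intensities per probe set of 7 Affymetrix ATH1 arrays, 6 with RNA and 1 with genomic DNA. Per the labels, RNA came from first-inflorescence primordia, 160 per sample, with 2 biological replicates for each of the CL, INT and CH flower types, and DNA came from leaves of plants without chilling. Per the labels, the authors calibrated the RNA data with the genomic DNA hybridization after Hammond and colleagues, a way to use an Arabidopsis array for another species by keeping probes that bind its DNA. The deposited intensity values are linear and positive, and every array had a mean of 500 once the lowest and highest 2% of probe sets were left out. The software that summarized probes and the DNA threshold are not given in the sources used here. The table held 22810 probe sets with a value on every array, so it does not show which probes the calibration left out. Arrays have no read depth, and the number of arrays sets the precision.

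The 64 control probe sets were left out of all tests, leaving 22746. Values were taken as log2(intensity + 28.2), the offset being 1 part in 10 of the median of all RNA values. It keeps dim probe sets from giving large differences and makes fold changes of dim genes too small. Array medians then ranged over 0.19 on the log2 scale, above the 0.1 set as the limit for leaving arrays as deposited, and the arrays were quantile normalized. Groups were compared with limma 3.58.1 in R 4.3.3, fitting the 6 RNA arrays with flower type alone and eBayes with a trend. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as threshold, and intervals are 95% intervals of the fit. The 3 contrasts and a moderated F-test over the 3 groups were run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on simulated data with 200 probe sets changed, and the set test on a simulated set shifted together. Both were drawn with independent noise, and the simulated result of the set test is not given here.

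Gene names came from the platform annotation, which gave 13513 probe sets 1 gene, 503 several and 8794 of the 22810 none; probe sets without a gene are unnamed here, and none was named from a probe set with several. Before the data were examined, the fits, alternatives, 19 gene lists and the rule for naming genes had been fixed. By that rule, where fewer than 5 genes passed in a contrast, the 10 lowest p-values were named among probe sets with 1 gene, with both arrays of one group above both of the other and a higher group mean above the median of all probe sets. List members were named by lowest p in CL against CH, at most 4 per list.

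The annotation named only 59 of the 366 list members, so the lists describe those members and not whole pathways. Of the others, 2 were dropped because the genes with neighbouring gene numbers lay on another chromosome. The 10 lists with at least 3 measured members that were tested covered floral organ growth and boundary, flowering time, stamen and tapetum, meiosis, auxin, gibberellin, cold and dehydration response, photosynthesis, expansins and xyloglucan enzymes, and flavonoids. The other 9 lists, among them floral organ identity with 0 members named by the annotation, were too small to test. A member is called measured here only where the annotation named it. The probes are of Arabidopsis, so a measured member may still have bound Cardamine RNA poorly. Genomic DNA intensities of single members are not given here. Members that it did not name may lie among the 8730 tested probe sets without a gene. A further 21 families, such as plastid-genome genes, were defined by gene symbol after the annotation had been seen and before any value was tested. The result of 1 family is not reported here. Sets were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists or families of a contrast, using 1 probe set per gene, that with the highest mean.

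The place of INT was measured on arrays not used to choose the probe sets, 500 in each direction. The alternatives were other normalizations and offsets, filters on dim probe sets and on genomic DNA intensity, other variance models, a replicate block, leaving out each array, a 2-fold threshold, probe sets with 1 gene, only the 4 arrays compared, 200 probe sets per direction for the place of INT, and a rank correlation. Added after the data were seen were the counts at an unadjusted p under 0.05 and 1 alternative, without CL replicate 1 and CH replicate 1 together.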

Results

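Inflorescence primordia of Cardamine kokaiensis, a wild relative of Arabidopsis, were compared among plants led to form 3 kinds of flower. Cleistogamous (CL) flowers stay closed and self-pollinate, chasmogamous (CH) flowers open, and flowers of the remaining kind were named intermediate (INT) by the submitters. RNA was hybridized to Arabidopsis ATH1 arrays, with 2 biological replicates per flower type, each from 160 pooled primordia, and 1 further array was hybridized with genomic DNA from leaf. CH flowers came from 14 days of chilling before germination, INT flowers from 14 days after germination and CL flowers from 28 days after germination, so flower type and chilling regime changed together. The 6 RNA arrays had median intensities from 260.8 to 301.8, and with 2 arrays per group the number of arrays limits the precision.

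The first comparison asked which transcripts differed between closed and open flowers. Under the naming rule, the gene with the lowest p-value was Cpn60beta2, a subunit of the chloroplast chaperonin. Its log2 intensity was 12.17 ± 0.25 (SD, n = 2) in CL and 10.95 ± 0.07 (SD, n = 2) in CH, a difference of 1.22 with a 95% interval from 0.76 to 1.68. JAL22, a jacalin-related lectin, measured 9.93 ± 0.18 in CL and 8.73 ± 0.34 in CH, a difference of 1.204. RTE1, a regulator of the ethylene receptor ETR1, measured 7.05 ± 0.03 in CL and 8.95 ± 0.11 in CH, a difference of -1.90 with an interval from -2.89 to -0.90. DI19, a zinc-finger protein of the drought response, was lower in CL by a smaller amount, with a difference of -0.78. Of the remaining 6 of the 10 genes with the lowest p-values, AT2G40760 (2.05), AT1G11470 (2.03), AT5G37710 (2.02), AT3G27210 (1.85) and AT3G59670 (1.502) had higher log2 intensity in CL, and AT5G08650 had lower (-1.35). None of these 10 genes passed the adjustment for 22746 probe sets; limma gave each an adjusted p of 0.9999.

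**Figure D1:**
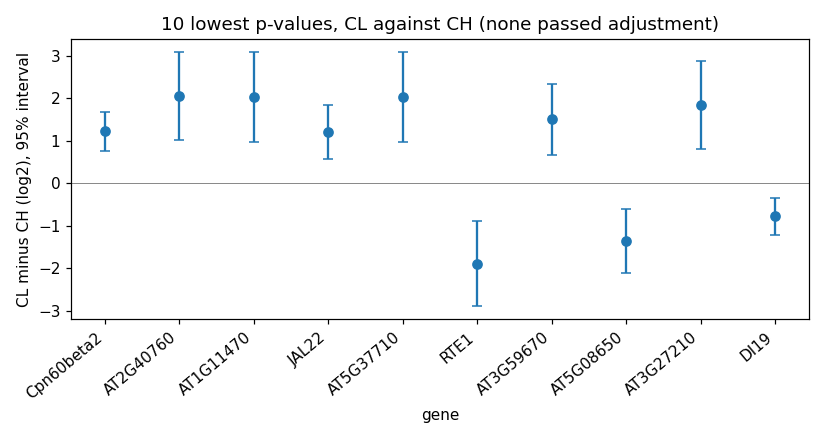
Difference in log2 intensity, CL minus CH, of the 10 genes with the lowest p-values under the naming rule. Points are the fitted differences over 2 arrays per group and bars their 95% intervals. The rule took low p-values and groups that did not overlap, so the place of the intervals follows in part from the choice. The interval of Cpn60beta2 runs from 0.76 to 1.68 and that of RTE1 from -2.89 to -0.90, but none of the 10 passed the adjustment for all probe sets.

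Over all probe sets, limma called 0 of 22746 different between CL and CH at the adjusted threshold of 0.05. At an unadjusted p under 0.05 there were 803 probe sets, 410 higher and 393 lower in CL, where 1137.3 would be reached by chance. That chance number assumes arrays that vary independently. The replicate differences of CL and CH correlated at 0.246 across probe sets, and the fit, which did not pair them, counted this shared part as spread. A count below chance therefore does not show that differences were absent. The lowest adjusted p was 0.489, for a probe set that the annotation used here does not name; it was singled out after its values were seen and measured 9.05 ± 0.17 in CL and 10.99 ± 0.16 in CH. Data were simulated with the means of these arrays, the spreads that the fit had estimated, independent noise and 200 changed probe sets. There the same fit recovered 0.5% of changes of 1 log2 unit, 54.5% of changes of 2 and 95% of changes of 3. The real CL and CH arrays shared replicate differences, so these rates describe the simulated data alone. A median probe set had a 95% interval of 0.90 log2 units on either side of its difference.

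Of the gene lists, the expansins and xyloglucan enzymes, which loosen and remodel the cell wall, came nearest to the threshold between CL and CH. Their 9 measured members had a mean difference of 0.55 log2 units and a median of 0.31, with 7 higher and 2 lower in CL. The adjusted p from camera was 0.0945 over 10 lists. XTH18 measured 7.76 ± 0.49 in CL and 5.85 ± 0.44 in CH, a difference of 1.91 with an interval from 0.41 to 3.41, and EXPA8 had a difference of 1.05 with an interval from -0.17 to 2.27. EXPA8 stood at 0.61 without CH replicate 1 and 1.49 without CH replicate 2, and the list mean at 0.36 without CL replicate 1 and 0.74 without CL replicate 2. The INT arrays share the estimate of the spread, and without either of them the adjusted p was 0.0349, while with all arrays and an estimated correlation it was 0.740. All 18 measured expansins of the annotation had 8 genes higher and 10 lower in CL, a median of -0.05, a mean of 0.17 and an upward test with an adjusted p of 0.861 over 21 families.

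No other list passed either. All 7 measured genes of floral organ growth and boundaries had lower means in CL, with a mean difference of -0.30 and an adjusted p of 0.485. Among them UFO, which acts in petal and stamen formation, differed by -1.09 with an interval from -2.68 to 0.51, and JAG, a growth regulator of lateral organs, by -0.29. UFO stood at 0.058 without CL replicate 1, JAG at -0.015 without CH replicate 1, and the list mean at -0.15 without CL replicate 1 and -0.45 without CL replicate 2. The 3 auxin genes had a mean difference of -0.51 and an adjusted p of 0.485, with GH3.3, an auxin-conjugating enzyme, at -1.30 and IAA29 at -0.35. GH3.3 stood at -0.69 without CH replicate 1 and IAA29 at 0.29 without CH replicate 2. For 5 gibberellin genes the mean difference was -0.20 and the adjusted p 0.568, with the receptor gene GID1B at -0.55 and SPY at -0.26. Without CH replicate 2 the list mean stood at -0.10, GID1B at -0.26 and SPY at 0.15, and without CH replicate 1 they stood at -0.30, -0.85 and -0.67. The 5 genes of the cold and dehydration response had a mean difference of 0.25 and an adjusted p of 0.897, COR15B standing at 0.44 and STZ at -0.39. COR15B stood at 0.035 without CL replicate 1, and without CL replicate 2 STZ stood at -0.075 and the list mean at 0.098. The 4 nuclear photosynthesis genes had a mean difference of 0.09 and an adjusted p of 0.945, with PSAN at 0.20 and RCA at 0.18. That mean was -0.12 without CL replicate 1, PSAN stood at -0.15 without CH replicate 2 and RCA at -0.30 without CH replicate 1. For 3 flavonoid genes the mean difference was -0.08 and the adjusted p 0.945, with BAN at -0.32 and DFR at 0.10. Without CH replicate 2 these differences were 0.049, 0.15 and -0.12.

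The lists of stamen and tapetum, meiosis and flowering-time genes did not pass between CL and CH. In the stamen and tapetum list of 6 genes, ROXY1 differed by -1.02 with an interval from -2.76 to 0.73 and ROXY2 by 0.35. Without CL replicate 2 ROXY1 stood at -0.57, ROXY2 at -0.10 and the list mean at 0.11, and without CL replicate 1 ROXY1 stood at -1.46. The median of that list was 0.15, its mean -0.05 and the direction of its test upward, with an adjusted p of 0.981. In the meiosis list of 3 genes, ATSPO11-1, which makes the breaks that start recombination, differed by 0.88 with an interval from -0.53 to 2.28, and RCK, a meiotic helicase, by -0.50. ATSPO11-1 stood at 0.041 without CH replicate 1 and 1.71 without CH replicate 2, RCK at 0.050 without CL replicate 1 and the list mean at -0.28 without CH replicate 1. The median was -0.36, the mean 0.01 and the test downward, with an adjusted p of 0.945. Of 4 measured flowering-time genes, AGL42 differed by -0.41 and FD by 0.25. AGL42 stood at 0.033 without CL replicate 2, FD at -0.096 without CH replicate 2 and the list mean at 0.26 without CH replicate 1. The list median was 0.0003, the mean -0.04 and the test downward, with an adjusted p of 0.981. In these 10 lists 0 members passed in CL against CH, either over all probe sets or adjusted over the list alone, and 2 members had an unadjusted p under 0.05.

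Transcripts of the plastid genome, a family defined from the annotation, formed the only set that passed between CL and CH. Their mean over 69 genes was 0.35 log2 units higher in CL, with 57 genes higher and 12 lower, and camera gave an adjusted p of 3.81e-05 over 21 families. With an estimated correlation of 0.218 among the genes the adjusted p was 0.951. The 3 genes with the lowest p-values had an unadjusted p under 0.05 and were named after their values were seen: psaJ, a subunit of photosystem I, differed by 0.70, rps4, a ribosomal protein, by 1.24 and rpoC1, a subunit of the plastid RNA polymerase, by 1.40. Leaving out single arrays moved rps4 from 0.69 without CL replicate 2 to 1.79 without CL replicate 1, and rpoC1 from 0.59 without CH replicate 2 to 2.21 without CH replicate 1.

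The plastid mean differed between arrays of one group as well. Relative to the mean of the 6 arrays it was 0.24 and 0.21 in the CL arrays, 0.11 and -0.37 in the CH arrays, and 0.16 and -0.34 in the INT arrays, naming replicate 1 first. The gap between the 2 CH arrays was thus 0.47, against the CL minus CH difference of 0.35. Without CH replicate 2 the difference was 0.11 and the adjusted p 0.572. The 25S ribosomal RNA control probe set was brighter on replicate 1 of each flower type, with intensities of 2652 and 145.9 in CH, 1961 and 629.6 in INT and 1823 and 392.9 in CL. Both arrays of CL lay above both of CH for 12 of the 69 plastid genes and below for 1. Chance gives 33.3% of genes one or the other, and over all probe sets it was 28.7%. The plastid share was lower than either. The close means of the CL arrays covered single genes that moved in opposite ways between them. From replicate 2 to replicate 1 of CL, psbA differed by 2.42 and rpl22 by -2.00, genes picked after their values were seen.

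**Figure D2:**
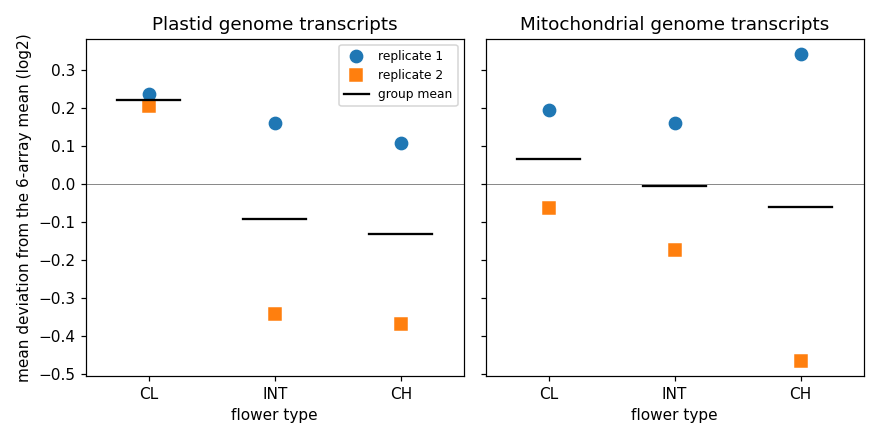
Mean deviation (log2) of plastid-genome and mitochondrial-genome transcripts from the mean of the 6 RNA arrays, by flower type; circles are replicate 1, squares replicate 2 and lines the group means. The CL arrays lie at 0.24 and 0.21 for plastid transcripts and the CH arrays at 0.11 and -0.37.

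The second comparison set INT against CH flowers, which had the same length of chilling at different stages. AT3G22240 had the lowest p-value of all probe sets, with a log2 intensity of 6.57 ± 0.12 (SD, n = 2) in INT and 9.26 ± 0.01 (SD, n = 2) in CH, a difference of -2.69 with an interval from -3.57 to -1.81. AT5G44770 differed by -2.76, AT3G61670 by -2.05, AT1G47310 by -1.69, AT3G28020 by -1.29 and AT3G50590 by -1.21. XIJ, a myosin heavy chain, measured 7.13 ± 0.18 in INT and 8.91 ± 0.13 in CH, a difference of -1.78. Higher means in INT were found for AT5G03560 (2.36), AT1G11470 (2.26) and AT1G43900 (0.87). Each of these 10 genes missed the threshold, with an adjusted p of 0.983. limma called 0 of 22746 probe sets, and 1082 had an unadjusted p under 0.05, 557 higher and 525 lower in INT.

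Among the lists, auxin genes stood nearest to the threshold in INT against CH, all 3 having lower means in INT, with a mean difference of -0.68 and a camera adjusted p of 0.206. All 4 nuclear photosynthesis genes had higher means in INT, with a mean difference of 0.40 and an adjusted p of 0.370. RCA, which encodes Rubisco activase, measured 12.07 ± 0.05 in INT and 11.01 ± 0.67 in CH, a difference of 1.06 with an interval from 0.35 to 1.76. It was the 1 list member that passed when adjusted over the list alone (limma adjusted p = 0.0350), and it did not pass over all probe sets, where 0 members did. Its difference was 0.58 without CH replicate 1 and 1.53 without CH replicate 2. The adjusted p over the list alone ranged from 0.00124 to 0.193 as single arrays were left out and passed only without CH replicate 2; it was 0.0631 with median scaling, 0.123 without the trend and 0.0569 with only the 4 arrays compared. Plastid-genome transcripts had a mean difference of 0.04 between INT and CH, with an adjusted p of 0.990. Leaving out single arrays moved that mean between -0.21 without INT replicate 1 and 0.29 without INT replicate 2, and without CH replicate 1 it was 0.28 with an adjusted p of 0.0221. In that setting the mitochondrial-genome transcripts also passed, with a mean of 0.46 and an adjusted p of 0.0221, against a mean of 0.06 and an adjusted p of 0.990 with all arrays. With all arrays and an estimated correlation the adjusted p was 0.994 for both families.

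The third comparison set CL against INT flowers, which were both chilled after germination, for 28 and 14 days. Cpn60beta2 had the lowest p-value under the naming rule. Its log2 intensity was 12.17 ± 0.25 in CL and 11.06 ± 0.12 in INT, a difference of 1.12 with an interval from 0.66 to 1.57. The plastid gene psaJ measured 12.89 ± 0.09 in CL and 11.89 ± 0.19 in INT, a difference of 1.00. AT3G22240 (1.81), AT1G07795 (1.79), AT2G31390 (1.60) and AT2G45340 (1.26) also had higher means in CL. Lower means in CL were found for AT3G56750 (-2.50), AT2G05370 (-2.09), AT3G59190 (-2.09) and AT1G78040 (-1.45). None of the 10 passed, each with an adjusted p of 0.985. limma called 0 of 22746 probe sets. An unadjusted p under 0.05 was found for 1001, 504 higher and 497 lower in CL, where 1137.3 would be reached by chance. The lowest p-value of all belonged to an unnamed probe set singled out after its values were seen, which differed by -3.06.

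Plastid-genome transcripts had a mean 0.31 log2 units higher in CL than in INT, with 54 of 69 genes higher, a camera adjusted p of 0.00477 and an adjusted p of 0.967 with an estimated correlation. The mean difference was 0.06 without INT replicate 2 (adjusted p = 0.752), and without CL replicate 2 it was 0.33 (adjusted p = 0.0778). None of the 10 gene lists passed in CL against INT. The expansins and xyloglucan enzymes again had the lowest camera adjusted p, 0.509, with a mean difference of 0.55, but this contrast used the same CL arrays. Their member XTH16 differed by 1.83, with an SD of 1.43 in CL.

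A joint F-test in limma over the 3 flower types called 0 of 22746 probe sets, with 956 at an unadjusted p under 0.05 and a lowest adjusted p of 0.996. Across probe sets, which are not independent replicates, the arrays of one flower type correlated at 0.914 in CL, 0.926 in INT and 0.918 in CH. CL replicate 1 and CH replicate 1 correlated at 0.931, and CL replicate 2 and CH replicate 2 at 0.939. Of the 15 ways to pair the 6 arrays, 9 gave a mean correlation within pairs at least as high as the flower types did, an exact one-sided p of 0.60, where the smallest p possible was 0.0667.

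**Figure D3:**
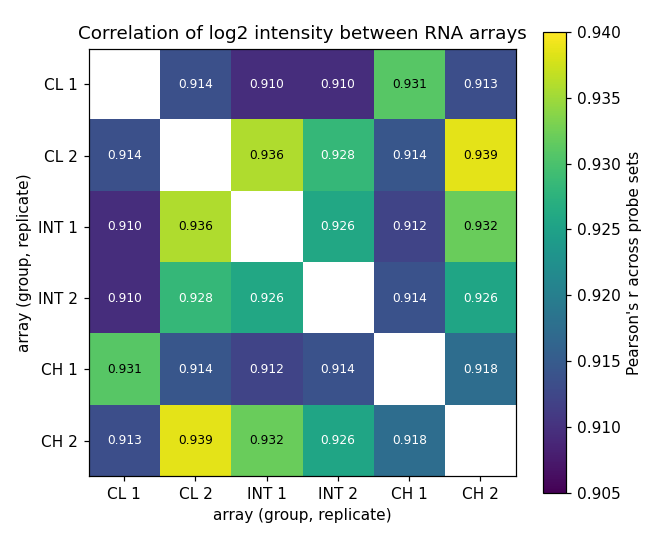
Pearson's r of log2 intensity between each pair of RNA arrays, across 22746 probe sets; rows and columns are arrays, named by flower type and replicate. The pair CL 2 and CH 2 has the highest r, 0.939, above the 0.914 of the 2 CL arrays.

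The place of INT flowers between CH and CL was sought with probe sets chosen on 1 CL and 1 CH array and measured on the arrays left over. On the arrays used for the choice, the 500 highest and 500 lowest probe sets differed by 1.84 to 2.06 log2 units. On the left-over arrays the distance from CH to CL in the chosen direction was 0.01 and 0.004 in the 2 pairings with equal replicate numbers, and -0.38 and -0.37 in the 2 with unequal numbers. The distance therefore gave no scale on which INT could be placed. From 36.3% to 51.7% of the chosen probe sets kept the sign of their difference.

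On the genomic DNA array, organelle genes were brighter than other named genes. Median log2 intensity was 16.15 over 69 plastid genes and 13.56 over 16 mitochondrial genes, against 8.47 over the 13421 other probe sets with 1 gene. Across the 22746 probe sets, log2 genomic DNA intensity correlated with mean RNA level at r = 0.32 and with the size of the CL to CH difference at r = -0.05. Median RNA log2 level was 8.73 for probe sets above the median genomic DNA intensity and 7.77 for the rest. Low RNA intensity was therefore not told apart from weak binding to Arabidopsis probes. The genomic DNA values are those of 1 array with no replicate.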

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

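Of the tests of explanations below, those of intensity-dependent scaling, of genomic DNA in replicate 1, of ribosomal RNA and of the spread between arrays were chosen after the result was seen; that of genomic DNA in the plastid pattern was written down before.

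Signals of 2 kinds lay outside the compared values. The genomic DNA array was in no fit of flower types, though it filtered probe sets in an alternative and, per the labels, served the authors' calibration. On it, plastid genes had a median intensity of 72634 and mitochondrial genes of 12116. The 25S ribosomal RNA control probe set, left out of the tests, was brighter on replicate 1 than on replicate 2 by 4.64 times in CL, 3.11 times in INT and 18.18 times in CH; with 1 array on each side these ratios have no error.

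Replicates 1 and 2 differed alike in CL and CH, the differences correlating at 0.246 across probe sets and at 0.449 across the brighter 11373. Both INT arrays correlated at 0.926 to 0.936 with replicate 2 of CL and CH. With replicate 1 of CL and CH they correlated at 0.910 to 0.914. The replicate difference of CL and CH therefore also enters the contrasts with INT. Scaling that depends on intensity is argued against as the whole cause, since 5.39% of the covariance of the deposited differences lay between 100 bins of mean level (bootstrap 95% interval from 4.71% to 6.83%), where that explanation needs over 50%. Genomic DNA left in the RNA of replicate 1 was taken to predict a replicate difference that rises with genomic DNA intensity. Over the 22654 probe sets not named as plastid or mitochondrial, the correlation was -0.124 (bootstrap 95% interval from -0.137 to -0.111). These probe sets are not independent. Those without a gene stayed in, so unnamed organelle probe sets may lie among them. Genomic DNA intensity itself rose with RNA level (r = 0.32), and the ratio of DNA to RNA intensity was not used. The test therefore cannot exclude genomic DNA in replicate 1. Ribosomal RNA carry-over as the whole cause is argued against by INT, whose replicate difference correlated at -0.0618 with that of CL and CH (interval from -0.0770 to -0.0464) although its 25S intensity also differed. Genomic DNA in replicate 2 was not tested, and an unrecorded day of collection or hybridization shared by these arrays may remain as an explanation; no biological explanation was tested.

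Plastid transcripts had a mean 0.351 log2 units higher in CL than in CH. Spread between arrays of one group may account for it, since the larger gap between 2 arrays of a group was 0.474. Genomic DNA left in the RNA stays open: across the 69 genes the change correlated with the ratio of DNA to RNA intensity at a Spearman's rho of 0.0581 (permutation p = 0.635), which decides nothing. The longer chilling and the flower type of the CL plants stay open too, untested, because the design joins them.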

How the results depend on the processing

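The unadjusted counts and the setting without CL replicate 1 and CH replicate 1 together were chosen after the data were seen, and the families after the annotation was seen and before values were tested. limma called 0 probe sets in each contrast and in the F-test under every alternative run, the lowest adjusted p ranging from 0.281 to 1.00 in CL against CH, 0.189 to 0.999 in INT against CH and 0.182 to 1.00 in CL against INT. Where an array was left out, the lone array of its group was assumed to vary like the others. With the replicate block 0 probe sets passed in each contrast and 893, 1248 and 1170 had an unadjusted p under 0.05, in the order CL against CH, INT against CH and CL against INT. The replicate numbers went together in CL and CH but not in INT. Replicate differences correlated at 0.246 between CL and CH, -0.0466 between CL and INT and -0.0510 between INT and CH. The block covered INT as well, so no fit paired CL with CH alone. Filters that removed probe sets lowered the unadjusted counts, to 441, 617 and 584 without the dimmest 3rd, 397, 528 and 484 in the upper range of genomic DNA intensity and 428, 646 and 563 with 1 gene. Fewer probe sets were tested there, but most shares of those tested were lower too: against 3.53%, 4.76% and 4.40% they were 2.91%, 4.07% and 3.85% without the dimmest 3rd, 3.49%, 4.64% and 4.26% in the upper range of genomic DNA intensity and 3.17%, 4.78% and 4.17% with 1 gene. The cause was not tested.

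Of the lists in CL against CH, the number passing was 0 or 1 as single arrays were left out and 0 otherwise. Of the families, 0 to 2 passed in CL against CH, 0 to 2 in INT against CH and 0 or 1 in CL against INT as single arrays were left out. With an estimated correlation and all arrays 0 families passed in any contrast, the plastid means being 0.35 in CL against CH, 0.04 in INT against CH and 0.31 in CL against INT with adjusted p of 0.951, 0.994 and 0.967. In the upper range of genomic DNA intensity 2 families passed in CL against INT, the plastid genome and the xyloglucan endotransglucosylases. The xyloglucan family had a mean of 0.92 and a camera adjusted p of 0.0457 there, against 0.52 and 0.376 over all probe sets. Without CL replicate 1 and CH replicate 1 together the plastid mean in INT against CH was 0.28 and the mitochondrial mean 0.46. Leaving out single arrays moved the plastid mean from 0.11 to 0.59 in CL against CH, -0.21 to 0.29 in INT against CH and 0.061 to 0.56 in CL against INT. The cause was not tested.

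The stamen and tapetum list, whose test and mean had opposite signs, tested downward with a mean of -0.072 as deposited, -0.039 with median scaling, -0.075 without offset, -0.20 in the upper range of genomic DNA intensity, -0.052 with the replicate block and -0.35 without CL replicate 1 and CH replicate 1 together. Leaving out single arrays turned the direction of 5 lists in CL against CH, with means from -0.34 to 0.26 for flowering time, -0.21 to 0.11 for stamen and tapetum, -0.28 to 0.30 for meiosis, -0.12 to 0.30 for photosynthesis and -0.21 to 0.049 for flavonoids. It turned the mitochondrial family, with means from -0.28 to 0.53, and it turned 13 of the genes named, their values ranging from -0.86 to 0.033 for AGL42, -0.096 to 0.61 for FD, -2.23 to 0.058 for UFO, -0.10 to 0.81 for ROXY2, -1.05 to 0.050 for RCK, -0.99 to 0.29 for IAA29, -0.67 to 0.15 for SPY, -0.15 to 0.56 for PSAN, -0.30 to 0.65 for RCA, -0.79 to 0.15 for BAN, -0.12 to 0.33 for DFR, -0.18 to 1.31 for JMT and -0.31 to 0.41 for GI. In the setting without CL replicate 1 and CH replicate 1 together flowering time stood at 0.18, RCK at 0.32, RCA at -0.44, JMT at -0.038 and GI at -0.24. The cause was not tested. Of 1090 gene values under alternatives, 1068 kept their direction and 0 passed. Much of that share was fixed in advance, so it does not measure how stable the directions were. Filters, variance models, the replicate block and the fit of only the arrays compared leave a difference as it is. So does leaving out an array of the group not compared. Genes named by lowest p-value under the rule had groups that did not overlap, so leaving out a single array could not turn them.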

Other observations

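Sugar transporters of the SWEET family had a mean 0.25 log2 units higher in CL than in CH, with 12 of 14 genes higher. camera gave an adjusted p of 0.335 over 21 families, and 0.951 with an estimated correlation; the mean was 0.48 without CL replicate 2 (adjusted p = 0.0274) and 0.025 without CL replicate 1 (adjusted p = 0.947). The 9 subtilases, a family of proteases, had a mean difference of 0.32 with 8 genes higher in CL and an adjusted p of 0.388, and the 9 xyloglucan endotransglucosylases of the annotation one of 0.36 with an adjusted p of 0.388. Without CH replicate 1 these means were 0.21 and 0.61, and without CH replicate 2 they were 0.43 and 0.12. The other families reported here, besides the plastid genome, had adjusted p values from 0.861 to 0.949, including 18 expansins, 8 higher and 10 lower in CL, with a mean of 0.17, a median of -0.05 and an upward test. The 16 mitochondrial-genome genes had a mean of 0.13, which was 0.53 without CH replicate 1 (adjusted p = 0.0112) and -0.28 without CH replicate 2 (adjusted p = 0.572). With all arrays and an estimated correlation the mitochondrial adjusted p was 0.951. In CL against INT, PDF1.2 was the 1 of 13 defensin-like genes that passed when adjusted over the family alone (limma adjusted p = 0.0455). It had a difference of -1.02 and a limma adjusted p of 0.985 over all probe sets. Its log2 intensity was low, 5.12 in CL and 6.14 in INT, where array medians before normalization were 8.17 to 8.37. The family had a camera adjusted p of 0.852.

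Members of lists too small to test were also measured. CLV3, a stem-cell signal of the shoot meristem, differed by 1.03 log2 units between CL and CH, with a 95% interval from 0.02 to 2.03. PHV, an organ polarity gene, differed by -0.49 with an interval from -1.03 to 0.06, WRKY53 by -0.47, JMT by 0.56, AUR2 by 0.32 and the clock gene GI by 0.05. WRKY53 stood at -0.19 without CL replicate 2 and -0.75 without CL replicate 1, and AUR2 at 0.50 and 0.15 in the same settings. Without CH replicate 1 JMT stood at -0.18 and GI at -0.31. None of these genes passed over all probe sets.

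Some genes differed alike between the replicates of CL and of CH, and were chosen after their values were seen. The plastid gene psbA was higher in replicate 1 than in replicate 2 by 2.42 log2 units in CL and 2.66 in CH, and by 0.59 in INT. XTH16, a cell-wall enzyme, was higher in replicate 1 by 2.02 in CL and 1.89 in CH, with -0.02 in INT. The plastid ribosomal protein gene rpl22 went the other way, with -2.00 in CL, -1.93 in CH and 0.37 in INT. Over all probe sets, 745 differed more than 2-fold between replicates in both CL and CH with the same sign, and 320 with opposite signs.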
